A study of Mus musculus with 4 samples.

How the data were processed

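RNA was sequenced from a mouse large pre-B cell line that lacks the transcription factors Irf4 and Irf8. Large pre-B cells are the dividing stage of B cell development that carries the pre-B cell receptor and grows in interleukin 7. Per the labels' protocols, the cells were grown on the stromal line OP9, a feeder layer, and transduced with a retrovirus that carried green fluorescent protein and a short hairpin RNA. The hairpin was directed at Myb (shMyb) or at luciferase, a control target (shLuc). Transduction was done in duplicate sets of 12 wells, the cells were kept for 72 hours in medium with 10 ng/ml of interleukin 7, and fluorescent cells were sorted. Total RNA went into a directional library kit and was sequenced in paired ends. Each of the 4 libraries was assigned to its group and replicate by its title, which gave 2 libraries per group. The duplicates were separate sets of wells of the same cell line, so p-values measure the spread between duplicate transductions of this line and not between lines or animals.

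The deposited files held raw read counts per gene symbol, 1 library per file, with 23420 rows each. The submitters' processing notes name FastQC, STAR, HTSeq and DESeq2 and the mm10 build, with neither versions nor roles. The annotation, the strand setting of the counting and any filter are not given in the sources used here. Reads from a gene and from an overlapping gene on the opposite strand may therefore not be separated, although the kit keeps strand. Reads from near-identical copies (the surrogate light chain genes Vpreb1 and Vpreb2, the Xlr4 family, ribosomal protein genes and their pseudogenes) may be split or lost, and their levels are uncertain. No row had a blank or no-feature name. In each file 27 gene symbols had been turned into calendar dates by a spreadsheet, and 2 such names stood on 2 rows. Those rows stayed in the totals and tests and are not named. Immunoglobulin heavy and kappa chain genes were not analysed here. Symbols were matched to GENCODE M21 (GRCm38, the assembly also called mm10), 21751 by name and 1248 through an older symbol, while 394 were not matched. Coordinates are those of that annotation and are 1-based. The deleted Irf4 and Irf8 alleles cannot be checked from counts per gene, and their transcripts are reported as counted.

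From the counts, genes were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, which left 12610 of the 16832 genes with a count. Libraries were scaled by TMM, dispersions were estimated with estimateDisp, and shMyb was compared with shLuc by glmQLFit with robust=TRUE and glmQLFTest, with group as the only term. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and a gene was called at an adjusted p below 0.05. CPM values (counts scaled to a common library total) use TMM-scaled library sizes. A standard error of a log2 fold change is its size divided by the square root of its F statistic. Values with ± are means and SD over 2 libraries. Total counts ran from 36573743 to 44682954 per library, and 3 counts, the limit that a count of 0 allows, were worth 0.0671 to 0.0820 CPM. That limit covers counting error only.

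Before the data were examined, 30 gene lists with 734 entries were fixed from textbook knowledge of pre-B cells, the cell cycle, metabolism and other cell types. In the files 8 entries stood under an older symbol, and 6 were not analysed here. Each list was described by its members that were higher, lower or not called, adjusted over all genes and adjusted over the list alone. It was also tested against all other genes with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the 30 lists. The rule for genes to name was fixed at the same point. It took the 26 genes of a focus list, Myb among them, then the 10 higher and 10 lower called genes with the largest fold change. Those 20 needed a mean of at least 10 CPM in the higher group and no overlap between the groups, and predicted gene models were left out. It further took up to 4 members with the smallest p from each list that passed or that marked another cell type. Some genes that this rule took are not reported here.

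The test was checked on simulated counts with the real means, library sizes and 2 libraries per group. The simulation changed few genes and drew counts at the trended dispersion. In the data 62.2% of tested genes were called, so the simulated rates need not hold there. Over 12610 genes, of which 200 were changed by these folds and 40 formed a list lowered by 0.3 on the log2 scale, it recovered 16% of genes changed 1.1-fold, 78% at 1.25-fold, 96% at 1.5-fold and 100% at 2-fold, and it called 7 of 12370 unchanged genes. Alternatives fixed in advance were RLE scaling, library totals alone, no low-count filter, a filter of 1 CPM in 2 libraries, robust=FALSE, DESeq2 1.42.0, limma-voom, a replicate block, leaving out each library, an adjusted p below 0.01 and a test against a 1.5-fold threshold. For lists they also included camera with an estimated correlation and fry. Alternatives added after seeing the data were a crossed replicate block, a correction for GC content and exon length, and a correction that also removed the trend with expression level. A count over genes of at least 10 CPM was added as well. The GC and length correction used a spline with 5 degrees of freedom fitted on genes of at least 1 CPM, and it was run again from 0.2 CPM after its first result was seen. Each fit kept its intercept, so it also rescaled the libraries. The median log2 fold change of all tested genes went from 0.0048 to -0.04, and to -0.08 from 0.2 CPM. The trend correction was fitted from 0.2 CPM, with and without the members of 3 lists.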

Results

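The data set compared gene expression in an Irf4- and Irf8-deficient large pre-B cell line that had received a hairpin directed at Myb with the same line that had received a control hairpin. Each group had 2 RNA-seq libraries. The shLuc libraries held 40701550 and 44682954 counts, and the libraries labelled shMyb held 38318335 and 36573743. Genes with at least 1 count numbered 15308 and 15099 in shLuc and 15480 and 15642 in the libraries labelled shMyb. Libraries of a group correlated at 0.996 (shLuc) and 0.997 (shMyb) across the log2 CPM of tested genes, which are not independent replicates. They differed by more than counting noise, with a chi-square per degree of freedom of 3.81 and 4.24, and each counted as a separate sample. Between the groups that value ran from 54.9 to 82.9.

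The first comparison asked whether the Myb transcript, which encodes a transcription factor of blood progenitors, was lower where its hairpin was used. It was not. Myb (chromosome 10, 21124935 to 21160984, minus strand, protein coding) was at 608 ± 11.5 CPM (SD, n = 2) in shLuc and 628 ± 15.7 CPM (SD, n = 2) in the libraries labelled shMyb. The single libraries had 616 and 600 CPM in shLuc and 617 and 639 CPM in shMyb. The log2 fold change was 0.046 (SE 0.04, 95% interval -0.03 to 0.12, edgeR adjusted p = 0.283). The related gene Mybl1 was at -0.07 (adjusted p = 0.357), while Mybl2, a cell cycle gene of the same family, fell by 0.22 on the log2 scale (adjusted p = 4.7e-05). Scaled by library totals alone, Myb was called higher (0.11, adjusted p = 0.0109), and so it was after correction for the trend with expression level (0.19, adjusted p = 1.5e-04). An exon of Myb overlaps Gm26577 on the opposite strand, and counts do not measure protein. Because Myb was not lower, every direction below is a difference between libraries that carry these labels, not a measured effect of lower Myb transcript.

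**Figure D1:**
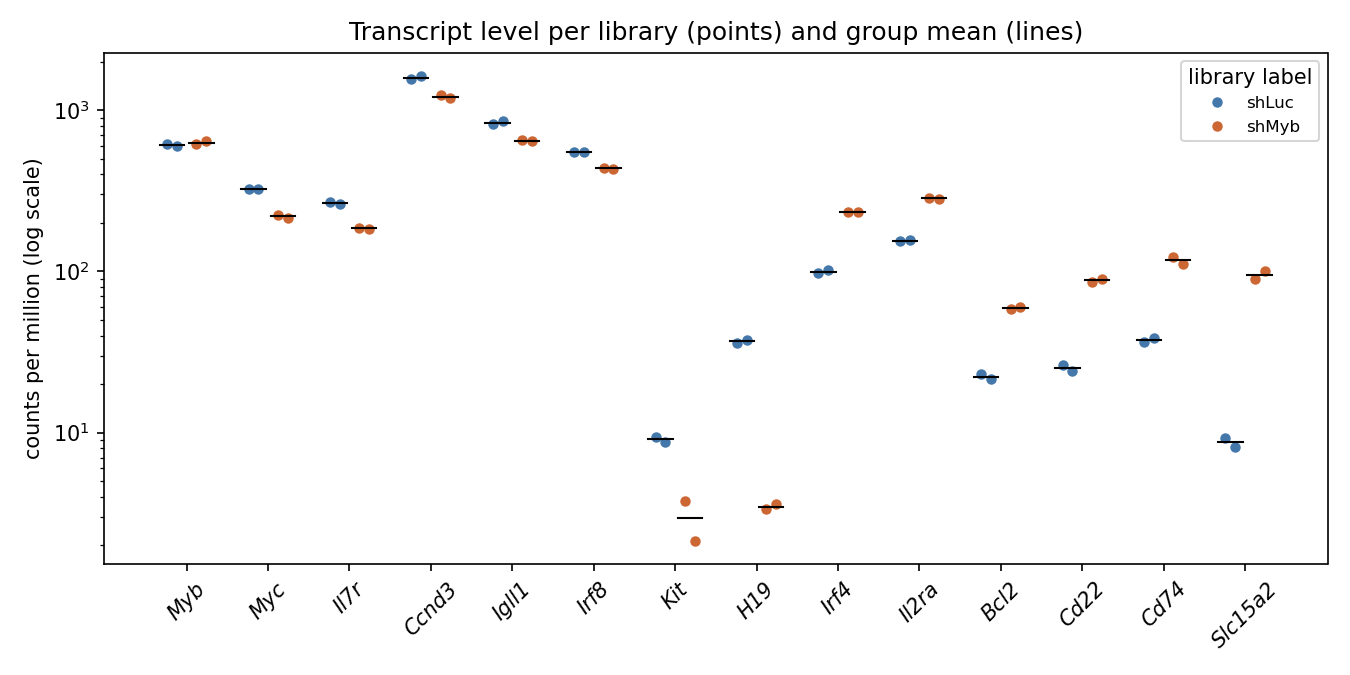
Transcript level of 14 named genes in CPM on a log axis, with a point per library and a line at the mean of the 2 libraries of each group. The Myb points of the groups lie together, at 600 to 639 CPM, while Irf4 rose from 99.3 to 232 CPM and H19 fell from 37.0 to 3.48 CPM.

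The libraries nevertheless differed across much of the transcriptome. The imprinted non-coding RNA H19 fell from 37.0 ± 1.18 to 3.48 ± 0.165 CPM (n = 2 each), and Bmpr1a, a receptor for bone morphogenetic proteins, fell from 55.4 ± 0.203 to 10.7 ± 0.168 CPM. The peptide transporter gene Slc15a2 rose from 8.70 ± 0.787 to 94.7 ± 7.52 CPM, and the X-linked gene Xlr4a rose from 0.343 ± 0.131 to 12.4 ± 0.656 CPM, on 10 and 19 counts in shLuc. The 10 genes with the largest rise ran from Xlr4a (log2 fold change 5.15, SE 0.18) to Capn5, a calpain protease gene (2.52, SE 0.08). They included Unc5cl (2.98), Zfp182 (3.04), Zfp951 (2.54), Cacna1e, a calcium channel gene (2.71), Sulf2, a heparan sulfatase gene (2.67), and Fam189a1 (2.53). The 10 genes with the largest fall ran from H19 (-3.41, SE 0.08) to Pcp4 (-2.21, SE 0.06). They included Gnai1, a G protein subunit gene (-3.02), Ston1 (-3.18), Sytl4 (-2.86), the repressor gene Klf12 (-2.84), Ly6a, which encodes the progenitor antigen Sca-1 (-2.35), Ccdc38 (-2.24) and Fgf13 (-2.23). Xlr4a belongs to a family of near-identical copies, and its level is uncertain. Among 12610 tested genes, 7849 were called (62.2%), 3855 higher and 3994 lower. Of these, 1021 were higher and 297 lower by at least 2-fold. The median size of a called change was 0.33 on the log2 scale, and the biological coefficient of variation was 2.90%. The groups did not overlap in 82.1% of tested genes, against 33.3% by chance for 2 against 2.

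Most of the surplus of large rises lay in genes of low abundance. Restricted to genes with a mean of at least 10 CPM in a group, 180 genes were higher and 89 lower by at least 2-fold. The median log2 fold change was 0.60 over the 944 genes up to 0.5 CPM and 0.37 over the 630 genes from 1 to 2 CPM. It was -0.01 over the 2354 genes from 10 to 30 CPM and -0.13 over the 619 genes above 300 CPM. Scaled by library totals alone, 60.1% of called genes were higher, against 49.1% with TMM. After the GC and length correction fitted from 0.2 CPM, which also rescaled the libraries, the share was 35.9%.

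**Figure D2:**
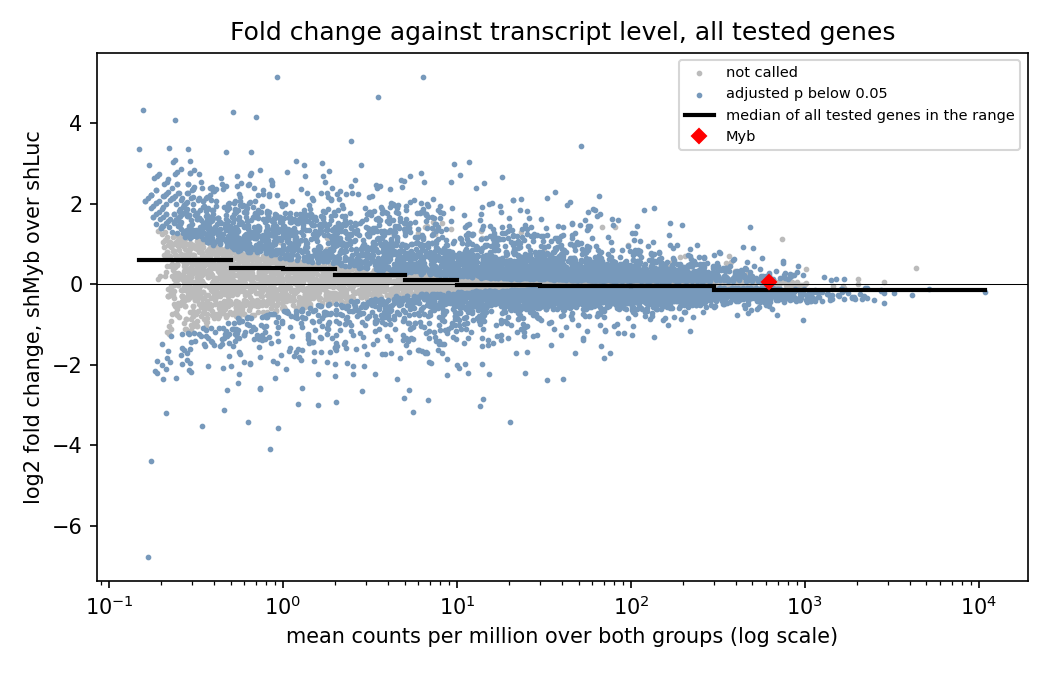
Log2 fold change of each of the 12610 tested genes (y axis) against its mean CPM over both groups (x axis, log scale), with called genes in blue, the others in grey, the median of each CPM range as a black line and Myb as a red diamond. The medians run from 0.60 at up to 0.5 CPM to -0.13 above 300 CPM.

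Among the 26 focus genes of pre-B cell growth, identity and survival, 11 rose, 10 fell and 5 did not pass the test. Adjusted over the list alone, 12 rose and 10 fell. The list as a whole did not pass camera (adjusted p = 0.152). Among its single genes, Myc, Il7r, Ccnd3 and Ccnd2 fell. Myc fell from 325 ± 0.453 to 219 ± 7.67 CPM (log2 fold change -0.57, SE 0.04, adjusted p = 1.7e-12), Il7r, a chain of the interleukin-7 receptor, from 265 ± 6.34 to 185 ± 2.52 CPM (-0.52, SE 0.04), and Ccnd3, cyclin D3, from 1594 ± 42.1 to 1213 ± 35.8 CPM (-0.39, SE 0.04). Ccnd2, cyclin D2, fell by 0.13, a call that ended with library totals (-0.06) and without shMyb replicate 2 (-0.09). The surrogate light chain genes Igll1 and Vpreb1 fell by 0.37 and 0.29, the chemokine receptor gene Cxcr4 fell by 0.29, and the growth factor receptor gene Kit fell by 1.62 from 9.11 ± 0.456 CPM. Irf8 fell by 0.34 and Irf4 rose by 1.23 (SE 0.04), from 99.3 ± 2.95 to 232 ± 0.526 CPM, as counted in a line deficient for both.

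Other genes of the focus list rose in the same libraries, among them genes for and against apoptosis. Bcl2, which opposes apoptosis, rose from 22.3 ± 1.26 to 59.5 ± 0.813 CPM (log2 fold change 1.42, SE 0.05, adjusted p = 8.6e-18). The pro-apoptotic genes Bmf and Bcl2l11 rose as well, by 0.63 and 0.50. Il2ra, the CD25 antigen of small pre-B cells, rose from 155 ± 0.763 to 285 ± 3.01 CPM (0.88, SE 0.04). The zinc finger genes Ikzf1 and Ikzf3 rose by 0.53 and 0.19, and the recombinase gene Rag1 by 0.29, although an exon of it overlaps another transcript on the same strand. Pax5 (0.21), Bcl2l1 (0.23) and Foxo1 (0.13) were called higher. After the GC and length correction these calls ended, at 0.08, 0.06 and 0.02, and from 0.2 CPM the values were 0.05, 0.01 and -0.0066. Both fits also moved the median of all tested genes, to -0.04 and -0.08. Pax5, Bcl2l1 and Foxo1 each fell by more than that median did, which had been 0.0048. Rescaling alone therefore does not account for their fall in value. Whether the calls ended through the rescaling or through the part fitted to GC content and length was not tested. The Foxo1 call also ended without shLuc replicate 1 (0.11). Rag2 (-0.11), Ebf1 (0.03) and Mcl1 (0.08) did not pass, and Ebf1 and Mcl1 were called higher with library totals (0.09 and 0.14) and with both trend corrections (Ebf1 0.13 and 0.12, Mcl1 0.18 and 0.16). Mcl1 was also called with limma-voom (adjusted p = 0.0463), the 1 CPM filter (0.0209) and the crossed block (0.00223).

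Of the 30 lists, 12 passed camera with the preset correlation, 6 higher and 6 lower. None passed with an estimated correlation (0 of 30, smallest adjusted p = 0.518, with 2 lists at an unadjusted p below 0.05). With 2 libraries per group that version has few degrees of freedom, so almost no list could pass it. The small pre-B list had an estimated correlation of 0.012, near the preset 0.01, yet its unadjusted camera p went from 2.1e-13 to 0.0188. For that list the lost call therefore does not by itself show an effect of inter-gene correlation. Other estimates lay far above the preset, at 0.67 for ribosomal proteins, 0.43 for cholesterol synthesis and 0.37 for the respiratory chain. Ribosome biogenesis was at 0.28, DNA replication at 0.22 and the pre-B cell receptor list at 0.13. For these lists the preset p-values may be too small. The MHC class II, B-lineage factor, NF-kB, anti-apoptotic and progenitor lists had estimates below the preset. With fry, which asks whether members move in a direction and does not compare them with other genes, 19 lists were called. Genes of ribosomes, respiration, sterol synthesis and DNA replication fell nearly as whole lists. Of 75 cytosolic ribosomal protein genes 73 fell and 2 were not called (median log2 fold change -0.32, camera adjusted p = 3.3e-16, adjusted p = 0.540 with an estimated correlation), among them Rps15a (-0.61), Rpl27 (-0.50), Rps16 (-0.45) and Rpl9 (-0.43). Adjusted over the list alone, 74 fell. All 39 nuclear-encoded respiratory chain genes fell (median -0.32, adjusted p = 1.4e-09, 0.540 with an estimated correlation), such as Ndufa4 (-0.57), Cycs, cytochrome c (-0.46), Cox7a2 (-0.44) and Cox5a (-0.39). Of 36 ribosome biogenesis and Myc-linked growth genes 35 fell (median -0.33, adjusted p = 4.2e-10, 0.540 with an estimated correlation), among them Srm (-0.51), Nhp2 (-0.49) and Odc1, ornithine decarboxylase (-0.47). Of 22 cholesterol synthesis genes 21 fell (median -0.41, adjusted p = 3.0e-10, 0.540 with an estimated correlation), among them Sqle (-0.65), Fdps (-0.62) and Cyp51 (-0.60). Of 40 DNA replication genes 34 fell and 6 were not called (median -0.23, adjusted p = 3.4e-06, 0.540 with an estimated correlation), among them Dut (-0.48), the helicase gene Mcm6 (-0.43), Pold2 (-0.39) and Tyms (-0.37). For the respiratory, biogenesis, cholesterol and replication lists the counts adjusted over the list alone were the same. Ribosomal protein genes are abundant, and abundant genes had lower fold changes in general. With that trend corrected, their median was -0.083, with 47 of 75 lower and 2 higher (-0.12, with 57 and 1, when the trend was fitted without 3 lists). The respiratory chain median was then -0.17 with 31 of 39 lower (-0.18 and 33), and the DNA replication median -0.14 with 33 of 40 lower and 1 higher (-0.15, with the same counts).

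Of B cell, antigen presentation, NF-kB and survival genes, 6 lists were called higher, some with members both ways. Of 25 surface and maturation genes of small pre-B and immature B cells 17 rose and 3 fell (median 0.56, camera adjusted p = 3.2e-12, 0.518 with an estimated correlation). Fcrla (2.05), the inhibitory receptor gene Cd22 (1.81), and Cd38 (1.64) were among them, and the antiproliferative gene Btg2 rose from 66.2 ± 2.15 to 142 ± 3.18 CPM. Of 10 MHC class II genes, which serve antigen presentation, 9 rose and none fell (median 0.68, adjusted p = 2.5e-05, 0.518 with an estimated correlation). The invariant chain gene Cd74 rose from 37.8 ± 1.58 to 117 ± 8.07 CPM, while the regulator gene Ciita rose by 1.69 on 1.03 ± 0.0387 CPM, and H2-Eb1 by 1.56. Myeloid cells express these genes too, and 9 of 14 myeloid markers rose as well (median 1.09). Of 35 transcription factors of early B cells 24 rose and 6 fell (median 0.19, adjusted p = 1.0e-03, 0.518 with an estimated correlation), with Klf2 at 1.43 and Sfpi1, which encodes PU.1, at 0.64. After the GC and length corrections that median was 0.08 from either cutoff, with 17 higher and 8 lower, or 15 and 8 from 0.2 CPM. Of 13 NF-kB response genes 9 rose and none fell (median 0.57, adjusted p = 0.00259, 0.530 with an estimated correlation), among them Birc3 (0.84), Nfkbid (0.81), Tnf (0.75) and Nfkb2 (0.57). Of 21 pre-B cell receptor components and proximal signalling genes 11 rose and 6 fell (median 0.16, adjusted p = 0.00796, 0.540 with an estimated correlation). The kinase genes Lyn (0.77), Prkcb (0.64) and Blk (0.62) rose, whereas the surrogate light chain genes Igll1 and Vpreb1 fell. That call ended after the GC and length correction fitted from 0.2 CPM (adjusted p = 0.0901), where 7 were higher and 8 lower at a median of 0.04. This fit also rescaled the libraries. The correction from 1 CPM gave a median of 0.09, the fit without shLuc replicate 1 gave 0.11 and the trend correction 0.25. Of 4 anti-apoptotic BCL2 family genes, Bcl2 and Bcl2l1 rose and Mcl1 and Bcl2l2 (0.08) did not pass (median 0.15, adjusted p = 0.00796, 0.540 with an estimated correlation). After the GC and length corrections Bcl2 alone was called, at list medians of 0.07 and 0.02, and with library totals all 4 were. Adjusted over the list alone, 3 rose in that list, and in the others the counts were the same.

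The progenitor list was called lower (adjusted p = 0.0224, 0.540 with an estimated correlation) with members that went both ways, 3 higher and 4 lower of 10, and a median of -0.06. Ly6a, Kit, Hmga2 (-1.45) and Angpt1 (-1.96, at 0.468 ± 0.0456 CPM in shLuc) fell. The call ended without shLuc replicate 1 (adjusted p = 0.0501) and without shMyb replicate 1 (adjusted p = 0.0739), and the Angpt1 call ended with DESeq2. The list median was 0.15 without shLuc replicate 1, 0.24 without shMyb replicate 1, 0.20 without shLuc replicate 2, -0.18 without shMyb replicate 2, and -0.43 with the trend correction.

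**Figure D3:**
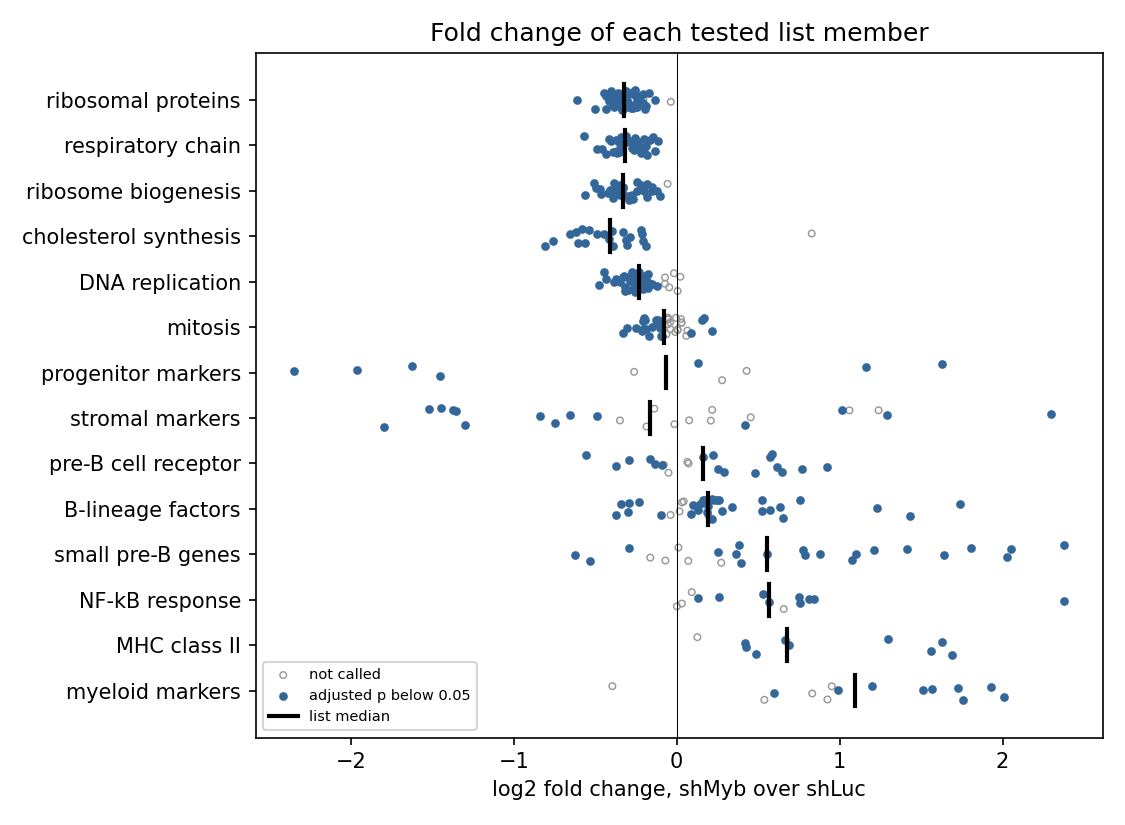
Log2 fold change (x axis) of each tested member of 14 lists, with filled points for called genes, open points for the others and a black line at the list median. Ribosomal protein genes centre on -0.32, while small pre-B genes centre on 0.56 with a wide spread.

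The other lists did not pass camera. Among genes of growth control and stress, 10 of 16 G1 cyclins and partners fell and 2 rose (adjusted p = 0.0546), and 11 of 21 unfolded protein response genes fell and 2 rose (0.0533). Of 29 interferon-stimulated genes 14 fell and 5 rose (0.0819), and of 40 mitosis genes 20 fell and 4 rose (0.146). Of 17 interleukin-7 and STAT5 genes 10 rose and 3 fell (0.282), of 7 CDK inhibitors 4 rose and 1 fell (0.741), and of 26 p53 response genes 9 rose and 7 fell (0.635). Of 24 chromatin regulators 10 rose and 8 fell (0.635), of 21 adhesion and migration genes 7 rose and 9 fell (0.745), and of 20 glycolysis genes 5 rose and 8 fell (0.828). Of 15 V(D)J recombination genes 6 rose and 5 fell (0.855), and of 9 pro-apoptotic BCL2 family genes 3 rose and 3 fell (0.635). The balance of mitosis genes turned with the trend correction, to 14 higher and 9 lower (12 and 11 when fitted without 3 lists), and with library totals it was 8 and 11. With the GC and length correction fitted from 0.2 CPM, the interleukin-7 list had 4 higher and 6 lower, the p53 list 6 and 11, the chromatin list 5 and 10, the V(D)J list 5 and 7, the CDK inhibitors 2 and 2 and the pro-apoptotic list 2 and 5. From 1 CPM the p53 list (7 and 10) and the chromatin list (7 and 9) turned as well. Both GC and length corrections also rescaled the libraries downward for shMyb, which moves such balances. The p53 list also turned without shLuc replicate 1 (3 and 5), shLuc replicate 2 (4 and 6) or shMyb replicate 2 (5 and 6). With the trend correction the glycolysis list had 8 higher and 5 lower and the adhesion list 11 and 8, and with library totals 7 and 5 and 9 and 8. Without shMyb replicate 2 the glycolysis list had 6 and 4 and the pro-apoptotic list 3 and 1. The focus list itself was at 0.152, with 8 higher and 10 lower after either GC and length correction, and it was called with the trend correction (0.00783, or 0.0125 with the trend fitted without 3 lists). The G1 list was called without shLuc replicate 1 (adjusted p = 0.0497), shLuc replicate 2 (0.0385) or shMyb replicate 1 (0.0427), and after both GC and length corrections (0.0218 and 0.0363). The unfolded protein list was called without shLuc replicate 1 (0.0317) or shMyb replicate 1 (0.0427), and the crossed block called both lists (0.0364 each). Adjusted over the list alone, 11 G1 genes and 12 unfolded protein response genes fell, and the other counts were the same. Median and camera direction differed in sign for the V(D)J list (median 0.02, lower) and the pro-apoptotic list (median -0.06, higher). Without shLuc replicate 1 the V(D)J median was -0.0042, and the pro-apoptotic median was 0.03 without shLuc replicate 2, 0.0077 without shMyb replicate 1 and 0.03 without shMyb replicate 2. For the glycolysis list the mean was 0.0042 and the camera direction lower.

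The lists of other cell types did not pass camera either. Of 24 stromal markers, which the OP9 feeder cells share, 4 rose and 10 fell (median -0.16, adjusted p = 0.393). With the trend correction the median was -0.55 and the list was called (0.0468), but not with the trend fitted without 3 lists (0.0535). The median was -0.03 without shLuc replicate 1, -0.30 without shLuc replicate 2 and -0.11 without shMyb replicate 1, and -0.33 and -0.37 after the GC and length corrections. Fn1, fibronectin, fell from 20.6 ± 2.90 to 7.18 ± 0.317 CPM, Thbs1 from 16.0 ± 0.234 to 5.87 ± 0.0501 CPM and Bgn from 10.6 ± 0.327 to 4.31 ± 0.109 CPM, whereas Thy1 rose from 12.3 ± 0.856 to 60.6 ± 2.69 CPM. Of 14 myeloid markers 9 rose and none fell (0.0546), several at low levels, where genes had higher fold changes in general. The median of all tested genes was 0.60 up to 0.5 CPM, 0.41 from 0.5 to 1 CPM and 0.24 from 2 to 5 CPM. Over both groups Cd14 and Cebpa lay from 0.5 to 1 CPM and rose by 1.73 and 1.76. Itgam lay from 2 to 5 CPM and rose by 1.51. Csf2ra lay from 10 to 30 CPM, where the median was -0.01, and rose by 0.60. Itgam rose from 1.08 ± 0.168 to 3.09 ± 0.302 CPM, Cd14 from 0.423 ± 0.144 to 1.40 ± 0.0180 CPM and Cebpa from 0.280 ± 0.136 to 0.940 ± 0.0494 CPM, while Csf2ra rose from 16.0 ± 1.01 to 24.2 ± 2.87 CPM. The myeloid list was called without shLuc replicate 1 (adjusted p = 0.0237) or shMyb replicate 1 (0.0342) with the replicate block (0.0409), and after both GC and length corrections (0.0218 and 0.0108). With the trend correction its median was 0.78, against 1.09, with 7 higher and 1 lower, and the list was not called (0.163). Of 11 T and NK cell markers 2 rose and 3 fell (0.832). The signalling genes Lat and Zap70 fell by 1.17 and 1.38, and Lck rose by 0.23, a call that ended after the GC and length correction fitted from 0.2 CPM (0.07). Of 6 plasma cell markers Irf4 and Mzb1 (0.31) rose and 4 fell, among them Xbp1 (-0.30) and Sdc1 (-0.31), with a median of -0.30 and a camera direction of higher (0.393). Of 5 erythroid and megakaryocyte markers 1 rose and 2 fell (0.741), with a median of 0.43 and a camera direction of lower. That median was 1.29 without shMyb replicate 1, 0.24 and 0.18 after the GC and length corrections and -0.14 with both trend corrections. Gfi1b fell by 0.56 and Nfe2 by 0.71, Gp1bb was at 1.40 on 3 to 17 counts per library, and the globin gene Beta-s, at 2.86 ± 1.94 and 7.38 ± 1.69 CPM, did not pass. The Nfe2 and Gp1bb calls ended with DESeq2, the Nfe2 call also without shMyb replicate 1 (-0.64), and the Gp1bb call without shLuc replicate 2 (0.72) without either shMyb library (1.33 and 1.46) and with both trend corrections (0.76). Beta-s was called higher without shLuc replicate 1 (2.28) without shLuc replicate 2 (0.79), with robust=FALSE (1.39, adjusted p = 5.4e-04) and with the crossed block (1.40). Adjusted over the list alone, 11 stromal markers fell, and the counts of the other cell type lists were the same.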

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

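The crossed block, the GC and length corrections, the trend corrections and the restriction to 10 CPM were chosen after seeing the data. The count of 7849 called genes stayed within 1.5 times except in the 1.5-fold threshold test (1124; 815 higher, 309 lower), which asks for larger changes, and ran from 6629 to 7483 when a library was left out (3084 to 3569 higher, 3505 to 3926 lower), where the lone library is assumed to vary like the other group. At 10 CPM or more, 2477 were higher among fewer genes. Counts changed by at least 2-fold, 1021 higher and 297 lower, became 606 and 194 with the 1 CPM filter, which tests fewer genes, and 180 and 89 at 10 CPM. They became 616 and 486 with the trend correction and 618 and 487 when it was fitted without the 3 lists, and 666 were higher in the threshold test. DESeq2 called 5894. Myb was not lower in any setting run, from 0.01 to 0.19. It was called higher with library totals (0.11, adjusted p = 0.0109) and the trend corrections (0.19 and 0.17). The same replicate numbers deviated in opposite directions (correlation -0.19) and were not taken to pair the samples. The replicate block called 7341 genes and 13 lists, and the crossed block 8593 genes and 14 lists. Of 30 lists, 12 passed, 0 with an estimated correlation, which had little power here, and 19 with fry. With that estimate adjusted p was 0.518 for the small pre-B, MHC class II and B-lineage factor lists, 0.530 for NF-kB and 0.540 for the other 8. The progenitor list ran from an adjusted p of 0.0170 to 0.0739 over the leave-one-out fits and lost its call without shLuc replicate 1 (0.0501) and without shMyb replicate 1, and the pre-B cell receptor list was at 0.0901 after the GC and length correction fitted from 0.2 CPM. Of 1748 comparisons of named genes 1715 counted as the same, 18 lost a call and 14 gained a call. The 1 that reversed was Foxo1, at -0.0066 (edgeR adjusted p = 0.914) after that correction. A change of sign where neither fit called the gene counted as the same. The cause was not tested. Depth limits the genes of a few counts, such as Gp1bb.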

Other observations

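Outside the fixed lists, some well expressed genes with large differences were picked after their values were seen. Cybb, the catalytic subunit of the phagocyte NADPH oxidase, rose from 23.3 ± 2.25 to 107 ± 1.19 CPM (n = 2 each) and Ncf1, another subunit, from 2.71 ± 0.224 to 11.8 ± 0.326 CPM. Their partners Ncf4 (log2 fold change 0.08) and Cyba (-0.10) did not pass the edgeR test. The lysosomal thiol reductase gene Ifi30, which acts in antigen processing, rose from 52.1 ± 1.40 to 186 ± 8.55 CPM, the guanine exchange factor gene Dock8 from 58.0 ± 0.177 to 215 ± 2.33 CPM and the cytokine receptor gene Csf2rb2 from 30.9 ± 0.246 to 103 ± 0.294 CPM. Capn2 fell from 109 ± 1.67 to 30.7 ± 0.511 CPM and Ramp3 from 115 ± 3.52 to 35.4 ± 0.442 CPM. Dntt, terminal transferase, which is a list member but falls outside the rule for named genes, fell from 1269 ± 28.5 to 683 ± 2.48 CPM.

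Except for the joint test of the expression trend and the first test of depth, whose drawing of counts was redone after its value was seen, the tests in this part and their bounds were chosen after the results were seen. The Myb transcript was not lower in the libraries labelled shMyb while 7849 genes differed. The choice of scaling does not hide a fall relative to other genes. The lowest Myb log2 fold change over TMM, RLE and library totals was 0.046 (SE 0.04), against a bound of -0.5. All of these scalings are relative, so a fall in Myb transcript per cell was not tested. An exchange of single libraries between the groups is argued against, since 4 of 4 libraries correlated best with their own group. A whole exchange of the labels is argued against only for a hairpin that lowers the Myb transcript by at least 0.5. Myb would then be higher by that bound in the libraries labelled shMyb, and its highest value over the edgeR settings was 0.19 (SE 0.03). A broad copy number difference carried by all cells is argued against. The largest median in size over 7588 windows of 51 neighbouring genes was -0.20 (SE 0.05), on chromosome 1, against 0.58 for a gain to 3 copies. Windows of this size cannot show a focal change or a change in part of the cells. A hairpin that acts on Myb protein, acts off target, or both stays open, as does an exchange of both libraries with outside samples, and no protein was measured here. With such a hairpin a whole exchange of the labels stays open too, and it would reverse every direction given.

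Ribosomal protein, respiratory chain and ribosome biogenesis genes were lower in those libraries, by a median of -0.32, -0.32 and -0.33. A bias of GC content and length does not account for all of it, since after that correction the highest of the 3 medians was -0.24. The SD of list medians was 0.03 over leave-one-out fits made without the correction. The correction also moved the median of all tested genes to -0.04. After correction for the trend with expression level the highest was -0.083, for ribosomal proteins, while the respiratory chain stood at -0.17 and ribosome biogenesis at -0.26. With the trend fitted on other genes, the medians were -0.12, -0.18 and -0.26, so the trend as the whole cause is argued against for ribosome biogenesis. For the respiratory chain the margin to the bound of -0.1 was narrow. The SD of 0.03 came from leave-one-out fits without the trend correction, which share libraries and may understate the error. The respiratory chain is therefore not decided. For ribosomal proteins the trend and a fall of their own cannot be told apart, since these genes are among the most abundant, and a fall linked to the lower Myc transcript is a hypothesis that was not tested.

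Genes of low abundance were higher in those libraries, and the 5166 genes below 0.5 CPM summed to 504 and 420 CPM in shLuc and 612 and 686 CPM in the libraries labelled shMyb. Genomic DNA was considered as a source. The 1491 olfactory, taste and vomeronasal receptor genes gained 22.3% as many CPM per kb as the other low genes. Without 3 neighbouring genes, which held 56.7% to 83.0% of the receptor counts, the gain was 2.02%. However, the receptor set kept genes without a count, with 23 to 27 counted per library, while the other low genes were kept only with a count. A uniform background therefore predicts less than 100%, and the gain alone cannot decide. A greater uniform background in the libraries labelled shMyb would also give counts to more receptor genes there. Those with a count numbered 27 and 23 in shLuc and 23 and 26 in the libraries labelled shMyb. For the receptor genes these numbers argue against a uniform background of genomic DNA, while an uneven one was not tested. The first bound of 25%, which the highest of the 4 library pairs (19.9% to 28.1%) exceeded, was raised to 50% after the value was known, and near-identical copies may lower the counts of receptor genes. Depth is argued against, since the larger total of the libraries labelled shMyb was 94.1% of the smaller shLuc total, although the first test, at equal totals, did not decide (a gap of 230 genes with a count against 290 within a group). RNA of other cells stays open. Fluorescent cells were sorted, and 10 of 24 stromal markers fell while 4 rose, but 9 of 14 myeloid markers rose and none fell. A broader transcription and RNA quality stay open too. Rn45s took 0.370% and 0.361% of the counts in shLuc and 0.441% and 0.579% in the libraries labelled shMyb.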
